A study of Mus musculus with 15 samples.

How the data were processed

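Expression was measured in Ba/F3-beta cells, a mouse IL-3-dependent pro-B cell line, on the 3 Affymetrix arrays of the murine U74 set (U74A, U74B and U74C). The 15 arrays covered 5 conditions, with 1 array per condition and design: control siRNA without IL-3, control siRNA with IL-3 for 30 min or 2 h, and Stat5 siRNA with IL-3 for 30 min or 2 h. Each array was assigned to its condition from its title. There was no array of Stat5 siRNA cells without IL-3 among those analysed here.

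The deposited values are linear probe set intensity values, which the authors computed with MAS5. The trimmed mean, leaving out 2% of probe sets at each end, lay between 150.04 and 150.1 on all 15 arrays, so the arrays had already been brought to one level. Detection calls and probe-level intensities were not used here, and the noise and call filters named in the series' design text were therefore replaced by a floor. No batch or scan date was given in the sources used here.

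Each array was scaled to a common trimmed mean, which moved the values very little. The floor was the signal that 14553 of the 36701 non-control probe sets reached on the highest of their 5 arrays, the number that passed the filters according to the design text. It came to 119.879. A probe set counted as measured in a comparison if at least 1 of its 2 arrays reached the floor. Signals under the floor were raised to it before the log2 ratio was taken, so a ratio with 1 such signal is a lower bound on the size of the change, written "at least". A change was called at 2-fold or more. These thresholds are selections by size and no tests.

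Gene names came from the platform annotation supplied with the arrays. It gave 1 symbol for 29131 non-control probe sets, several for 724 and none for 6846, and 0 symbols needed updating through the gene table of the GRCm38.p6 assembly, which was used for names only. No gene was named from a probe set with several symbols. The value of a gene was the median over its measured probe sets. Probe sets ending in _f_at, _r_at, _i_at or _x_at were treated as those that can cross-hybridise, and entered only where the gene had no other. Probe sets ending in _s_at were not put in this group. All columns of sample values were used.

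The rule for naming genes, the gene lists and the alternatives, except where stated, were fixed before the data were examined. Named are Stat5a and Stat5b, the 12 genes with the largest rise and the 8 with the largest fall per comparison, the genes induced by IL-3 and lower with Stat5 siRNA, and 2 to 4 members of each gene list with the largest ratios. The 23 gene lists covered STAT5 targets known in blood cells, immediate early genes, ribosome biogenesis and MYC-linked genes, G1/S cell cycle, G2/M cell cycle, FOXO-linked and growth arrest genes, apoptosis regulators, cholesterol and fatty acid synthesis, glycolysis and glucose uptake, amino acid and ATF4 response, interferon response, JAK-STAT pathway and cytokine receptors, MAPK feedback, NF-kB linked and cytokine genes, ribosomal proteins, housekeeping genes, mitochondrial respiration, heat shock, and markers of pro-B and B lineage, myeloid and mast, T and NK, erythroid and megakaryocyte, and fibroblast and epithelial cells. For each list with at least 5 measured genes, the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean log2 signal in 10 bins. A list below percentile 2.5 or above 97.5 is said to stand apart. This describes these arrays and is no test between conditions. Lists can share members, so their calls are not independent. Dusp1, Dusp5, Phlda1 and Ier3 are on both the immediate early and the MAPK feedback list. Dusp5 and Myc are on both the STAT5 target and the immediate early list.

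With 1 array per condition and design, no p-value was computed, and the number of arrays limits the precision. Technical spread was read from control probe sets shared by the 3 designs and from pairs of probe sets of 1 gene. For probe sets induced by IL-3 and lower with Stat5 siRNA, the control IL-3 array enters both ratios. Their count was therefore set beside the count with the siRNA labels of the 2 IL-3 arrays exchanged, the mirror count (lower with IL-3 and higher with siRNA), and 200 simulations without any siRNA effect whose noise was drawn from the probe set pairs. Selection was by probe set, and where the gene's own value did not pass, that value is given.

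The steps were tested on simulated data. In a simulation of the IL-3 comparison at 2 h with 200 changed probe sets and a noise SD of 0.2, the 2-fold threshold recovered 97.0% of 4.0-fold changes among 13052 probe sets tested and 86.0% of 2.5-fold changes among 13013. That noise is the SD of 1 array and gives a ratio less spread than the SD of 0.35 measured between probe sets of 1 gene in this comparison, so recovery in the data is likely lower. All changed probe sets had a signal of at least 2 times the floor without IL-3, so recovery among dimmer ones was not tested. Of 100 random lists of 30 genes, 8 fell outside percentiles 2.5 to 97.5. Alternatives were median and quantile scaling, the floor halved, doubled or set per design, signals not raised to the floor, the brightest probe set per gene, and a 1.5-fold siRNA threshold. Results on U74A and U74B only and without cross-hybridising probe sets were added after seeing the data. So were random lists matched on the IL-3 ratio of the same time, in which each member was replaced by 1 of the 100 genes nearest to it in that ratio, because the control IL-3 array enters both ratios. Those 100 genes could include other members of the same list. For the members with the largest IL-3 ratios they lay mostly lower in that ratio. A call that ended in this setting therefore does not show that the shared array produced it. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.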

Results

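Gene expression in IL-3-stimulated Ba/F3-beta cells was compared between cells given a control siRNA and cells given siRNAs against Stat5a and Stat5b, 2 closely related transcription factors that IL-3 receptor signalling activates. The series was designed to find genes that IL-3 induces through these factors. The 15 arrays gave 5 conditions on each of 3 array designs, and 14553 of 36701 non-control probe sets reached the floor, 4597 on U74A, 5317 on U74B and 4639 on U74C. Every condition had 1 array per design, so no difference reported here has a replicate check.

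Arrays of 1 design correlated between 0.893 and 0.977. The signal ratio of the 3' to the 5' control probe sets reached at most 1.19 for actin and 0.858 for Gapdh, and lay between 2.64 and 5.49 for the transferrin receptor Tfrc. Pairs of probe sets of 1 gene gave a spread for a single log2 ratio, an SD, that was wider on U74C than on U74A in every comparison. For the siRNA comparison at 30 min it was 0.22 on U74A, 0.21 on U74B and 0.32 on U74C. In that comparison 4.89% of pairs within U74C differed by 2-fold or more, against 0.515% within U74A.

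The siRNA targets were lower in Stat5 siRNA cells. The brighter of the 2 Stat5a probe sets had a signal of 548 with control siRNA and 277 with Stat5 siRNA at 30 min, and 475 and 255 at 2 h, which left 50.6% and 53.6% of control. The other Stat5a probe set had 316 and 150 at 30 min, and 254 and 96.5 at 2 h, the last under the floor. Stat5a was read only from these 2 probe sets, both of a kind that can cross-hybridise. The U74B probe set of Stat5b fell from 500 to 166 at 30 min, 33.2% of control. At 2 h its signals were 177 and 126, 71.3% of control. In control siRNA cells this probe set had already gone from 536 without IL-3 to 177 after 2 h, 33.0% of the unstimulated signal, so the siRNA difference at 2 h was measured against a low level. The Stat5b probe set on U74A stayed under the floor on all 5 arrays.

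**Figure D1:**
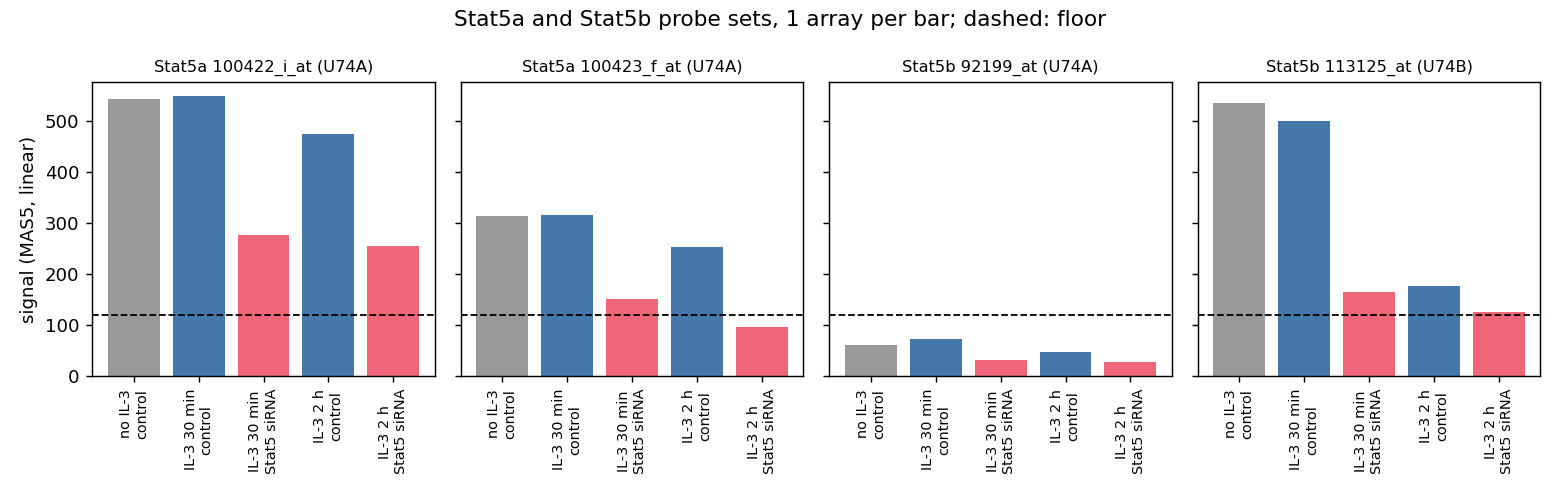
Linear MAS5 signal of the 4 Stat5a and Stat5b probe sets in the 5 conditions, 1 array per bar, with the floor of 119.879 as a dashed line. The brighter Stat5a probe set lies at 277 and 255 with Stat5 siRNA against 548 and 475 with control siRNA, and the U74A probe set of Stat5b lies under the floor throughout.

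Within 30 min IL-3 raised immediate early genes, the first genes transcribed after a growth signal. Egr2, a zinc finger transcription factor, rose at least 18.7-fold and Fos, a subunit of AP-1, at least 16.2-fold. Csrnp1 rose 12.7-fold, Dusp1, a phosphatase that inactivates MAP kinases, 12.2-fold, and Ier2 11.1-fold. Cish, a feedback inhibitor of cytokine receptors and a known STAT5 target, rose at least 9.15-fold. Junb rose at least 7.65-fold, Phlda1 at least 7.01-fold, the activation marker Cd69 at least 6.52-fold, Dusp5 6.26-fold, Ppil6 at least 5.71-fold and 1700113H08Rik 4.63-fold. Junb, Ppil6 and 1700113H08Rik were read only from probe sets that can cross-hybridise. Ddit4, a stress-induced inhibitor of mTORC1, fell by 1.69 on the log2 scale. The other genes with large falls were E330020D12Rik (-1.55), AV205837 (at least 2.87-fold lower), Smpd3 (at least 2.67-fold lower), Lrmda (-1.39), Ttll11 (-1.38), BC049762 (-1.37) and Fam217a (-1.37). Of these 8 genes 6 were read only on U74C, and AV205837, Ttll11, BC049762 and Fam217a only from probe sets that can cross-hybridise.

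At 30 min 109 of 13277 measured probe sets were 2-fold or more higher and 78 lower. U74C gave 65 of those higher and 66 of those lower, and U74A and U74B alone gave 44 and 12. By gene, 58 of 8155 were higher and 28 lower. The design text states 164 induced genes at this time, under filters that were not applied here. Of 29 measured immediate early genes 16 rose and 0 fell, with a median log2 ratio of 1.46 at percentile 100 of random lists. Of 17 STAT5 targets 7 rose, with Cish, Dusp5 (2.65) and Myc (at least 2.14) leading, and the list's median of 0.12 lay at percentile 97.56. Median scaling ended that call, while the median was 0.27 to 0.50 with the brightest probe set per gene, with the other floors and with signals not raised to the floor. Of 12 MAPK feedback genes 5 rose, among them Dusp1 (3.61) and Ier3 (2.11), with a median of 0.37 at percentile 100, but the median was -0.026 with the floor halved, 1.36 with the floor doubled and 1.22 with signals not raised to the floor. The FOXO-linked list held Btg2 (1.57) and Cdkn1a (1.36), both inhibitors of proliferation, and its median of 0.03 did not stand apart. The JAK-STAT list had a median of 0.09 at percentile 97.57, a call that most other settings ended. G2/M genes had a median of 0.11 at percentile 99.59 with 0 of 34 past 2-fold, and the call ended with the brightest probe set per gene (percentile 94.9).

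After 2 h of IL-3 the cells showed higher ribosome biogenesis genes and lower growth arrest genes. Cish was at least 13.1-fold higher and Id1, an inhibitor of basic helix-loop-helix factors, at least 7.60-fold. Phlda1 rose at least 6.61-fold and Lrp12 5.76-fold. Tsr1, Gnl3 and Nop2, which act in ribosome assembly or the nucleolus, rose 5.50-fold, 5.29-fold and 4.50-fold. The transcriptional repressor Bhlhe40 rose 5.44-fold, Xbp1, a regulator of the unfolded protein response, 4.67-fold, Ikzf4 4.64-fold, Kcnk5 4.57-fold and Slc25a33 at least 4.51-fold. Among the falls, Ccng2, a cyclin linked to cell cycle arrest, was at least 8.80-fold lower. Gchfr was 8.52-fold and Amhr2 at least 4.54-fold lower, both on probe sets that can cross-hybridise. Arhgef18 was at least 4.64-fold lower, Rnf125 4.60-fold, Trp53inp1 4.39-fold, Nr2c2 4.12-fold and Ddit4 4.08-fold.

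At 2 h 338 of 13596 probe sets were higher and 278 lower, and on U74A and U74B alone 224 and 182. By gene, 203 of 8294 were higher and 135 lower. The design text states 553 induced genes. Of 51 measured ribosome biogenesis and MYC-linked genes 16 rose and 0 fell (median 0.51, percentile 100), with Rrs1 at least 2.13 in log2 ratio. Of 19 STAT5 targets 9 rose (median 0.88, percentile 100), among them Bcl2l1, a survival factor (at least 2.10), and the kinase gene Pim2 (at least 1.78). Of 26 immediate early genes 12 were higher and 1, Klf6 (-1.14), was lower (median 0.83, percentile 100). Of 15 MAPK feedback genes 6 rose (median 0.70, percentile 100), including Dusp4 (at least 2.14) and Dusp6. With signals not raised to the floor the medians of the STAT5 target, immediate early and MAPK feedback lists were 1.78, 1.30 and 1.19. Of 25 FOXO-linked and growth arrest genes 4 fell (median -0.58, percentile 0): Ccng2, Trp53inp1, Tob1 (-1.95) and Gadd45a (-1.37). G1/S genes had a median of -0.50 at percentile 0, with Cdc6 (-1.70) and Cdt1 (-1.37), both needed to license replication origins, the 2 of 27 that fell. G2/M genes had a median of -0.30 with 0 of 34 past 2-fold. The amino acid and ATF4 list (0.16, with Atf4 at 1.13 and Ddit4 at -2.03), the NF-kB list (0.37) and the JAK-STAT list (0.14) also stood apart upward. The first call ended with the floor halved or doubled, the second with the floor halved (median -0.059) or set per design (0.069) and with signals not raised, and the third with median and quantile scaling and on U74A and U74B only. Erythroid and megakaryocyte markers had a median of -0.31 at percentile 3.01, with Klf1 (-1.69) the 1 of 8 that fell, and stood apart downward with most other settings.

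**Figure D2:**
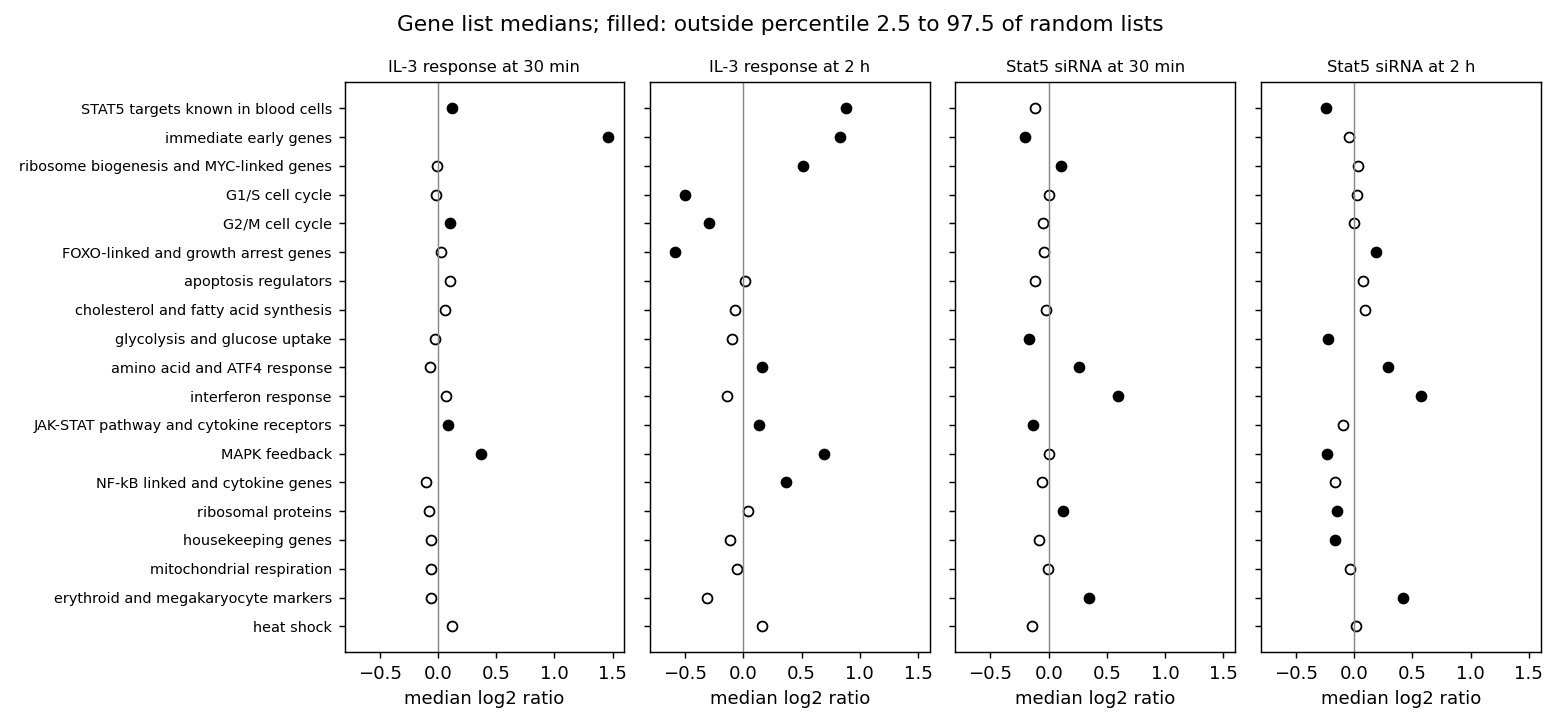
Median log2 ratio (x) of 19 gene lists (y), 1 panel for each of the 4 comparisons, with filled circles where the median lies in the outer 2.5% of random lists on either side. Immediate early genes lie at 1.46 for IL-3 at 30 min, and the interferon list lies at 0.59 and 0.57 in the siRNA comparisons.

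Stat5 siRNA cells had higher interferon response genes and lower Cish at 30 min of IL-3. Ccl5, a chemokine, was at least 13.8-fold higher, with a signal of 1660 against 61.4. Irf7, a master regulator of type I interferon genes, was at least 3.73-fold higher, Ddit3, a transcription factor of the stress response, at least 2.75-fold and Irf1 2.57-fold. Ttll11 (1.43), Grid1 (1.42), Bpifa5 (1.41), Akt1s1 (1.39), Allc (at least 1.28), AV205837 (at least 1.26), Cst12 (1.25) and Zfpm2 (at least 1.24) followed in log2 ratio. Of the 12 genes named as higher, 8 were read only on U74C, and Ttll11, Akt1s1, AV205837 and Cst12 only from probe sets that can cross-hybridise. Ttll11, Akt1s1 and AV205837 were also 2-fold or more lower with IL-3 at 30 min, and the control IL-3 array enters both ratios. Stat5b (-1.59) and Cish (-1.49) were among the 8 largest falls, with Egflam (at least 5.55-fold lower), 1700113H08Rik (-2.09), Fastk (-1.79), Fbxo44 (at least 3.41-fold lower), Psmc3 (-1.71) and Man2b2 (at least 2.95-fold lower). Of these 8 falls 5 were read only on U74C, and the value of Psmc3 also came from a U74C probe set. Egflam, 1700113H08Rik and Fastk were read only from probe sets that can cross-hybridise, and Fastk turned to 0.23 with the floor halved. Psmc3 was 0.031 on U74A and U74B only.

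At 30 min 55 of 13216 probe sets were higher with Stat5 siRNA and 59 lower, of which U74C gave 37 and 44. By gene, 25 of 8124 were higher and 31 lower. Of 24 measured interferon response genes 7 rose, 0 fell and 22 had ratios above 0, with a median of 0.59 at percentile 100. A signal under the floor was present in 6 of the 24, and which array reached the floor can set the sign there. Irf7, Irf1, Oas2 (1.23) and Oasl2 (at least 1.22), both of the oligoadenylate synthetase family, had the largest ratios. Amino acid and ATF4 response genes had a median of 0.26 at percentile 100, with Ddit3 the 1 of 30 past 2-fold. Erythroid and megakaryocyte markers had a median of 0.35 at percentile 99.93, with alpha globin Hba-a1 (1.23) the 1 of 9 past 2-fold. Ribosome biogenesis genes (0.11) also stood apart upward, and so did ribosomal proteins (0.12), a call that ended with quantile scaling, with a halved floor and without cross-hybridising probe sets. Immediate early genes (-0.20), glycolysis genes (-0.17) and the JAK-STAT list (-0.14) stood apart downward. Among random lists matched on the IL-3 ratio, an alternative chosen after seeing the data, the immediate early list lay at percentile 72.7, the JAK-STAT list at 3.09 and ribosomal proteins at 94.8. These calls ended in that setting, whose random lists can hold other members of the same list. In the JAK-STAT list 4 of 32 fell: Stat5b, Cish, Socs1 (at least 2.31-fold lower) and Stat5a (-1.03). The STAT5 target list, with 2 of 17 lower, had a median of -0.12 at percentile 3.61. It did not stand apart, but did with 3 other floors and with signals not raised to the floor, and it lay at percentile 34.5 of lists matched on the IL-3 ratio. In the NF-kB and cytokine list, whose median was -0.06, Ccl5 rose and Ccl9 (at least 2.10-fold lower) fell.

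At 2 h the interferon response genes were again higher in Stat5 siRNA cells, and the STAT5 targets Tnfrsf13b, Cish and Pim2 were lower. Ccl5 was at least 10.3-fold higher, Oasl1 3.36-fold and Oasl2 at least 3.31-fold. Ddit3 was at least 3.04-fold higher, Irf7 at least 2.75-fold, the interferon-inducible GTPase Gbp7 2.66-fold and Hba-a1 2.62-fold. The remaining genes of the 12 were 1700129C05Rik (at least 2.49), Amhr2 (at least 1.70), Psmc3 (1.66), Gchfr (1.49) and 2310026I22Rik (at least 1.42) in log2 ratio. All but Psmc3 of these were read only from probe sets that can cross-hybridise, and Psmc3 was -0.082 on U74A and U74B only. All of these were also lower with IL-3 at 2 h in control siRNA cells, from -1.33 or lower for 1700129C05Rik to -3.09 for Gchfr. The control IL-3 array enters both ratios, so a low signal on that array would give both the fall and the rise. Tnfrsf13b, a receptor for the B cell factors BAFF and APRIL, was 3.25-fold lower and S100a4, a calcium-binding protein, 2.84-fold lower. Gpr137 was lower on U74B (-1.53), and Naaa (-1.56) and Nlrp9b (-1.41) were lower on U74C probe sets. A U74B probe set of Naaa that can cross-hybridise gave -0.46. Ces1d, Zfpm2 and Syt4 were at least 3.34-fold, 2.89-fold and 2.83-fold lower, each on U74C and, for Ces1d and Syt4, only on probe sets that can cross-hybridise.

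At 2 h 84 of 13308 probe sets were higher with Stat5 siRNA and 75 lower, of which U74C gave 50 and 45. By gene, 41 of 8132 were higher and 35 lower. Of 27 interferon response genes 7 rose, and all 27 had ratios above 0, with a median of 0.57 at percentile 100, and of 0.95 with signals not raised to the floor. A signal under the floor was present in 12 of the 27, and which array reached the floor can set the sign there. Of 20 STAT5 targets 3 fell and 0 rose, Tnfrsf13b, Cish (-1.28) and Pim2 (-1.05), and the median of -0.24 lay at percentile 0.02 of lists matched on signal, and was -0.39 with signals not raised to the floor. It lay at percentile 8.65 of lists matched on the IL-3 ratio, where it did not stand apart, and all 338 probe sets induced at 2 h had a median siRNA ratio of -0.21. Amino acid and ATF4 genes had a median of 0.30 at percentile 100, with Ddit3 and Trib3 (at least 1.14) past 2-fold. FOXO-linked and growth arrest genes (0.19) and erythroid and megakaryocyte markers (0.42) stood apart upward. Glycolysis genes (-0.22), MAPK feedback genes (-0.23), ribosomal proteins (-0.15) and housekeeping genes (-0.17) stood apart downward. Quantile scaling ended the calls for ribosomal proteins and housekeeping genes. The former also ended without cross-hybridising probe sets and the latter with the floor halved or doubled, and a doubled floor ended those for FOXO-linked (percentile 90.3) and MAPK feedback genes (6.17). Among lists matched on the IL-3 ratio FOXO-linked genes lay at percentile 79.5 and MAPK feedback genes at 22.3, which ended both calls, while ribosome biogenesis genes (0.037) came to stand apart at 99.0. B2m, a housekeeping gene that interferon also induces, was higher (1.32). The JAK-STAT list (-0.09, percentile 4.18) stood apart only with quantile scaling, and the NF-kB list (-0.16) did not.

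The siRNA ratios at 30 min and 2 h share no array. At both times 9 genes were 2-fold higher (Ccl5, Oasl1, Oasl2, Ddit3, Irf7, Hba-a1, Oas2, Bst2 and Grid1) and 4 were lower (S100a4, Cish, Bhlhe40 and 1700113H08Rik). Across 7699 genes measured at both times, which are not independent replicates, Pearson's r was 0.204 and Spearman's rho 0.164. Of 52 genes changed at 30 min and measured at 2 h, 41 had the same sign at 2 h.

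**Figure D3:**
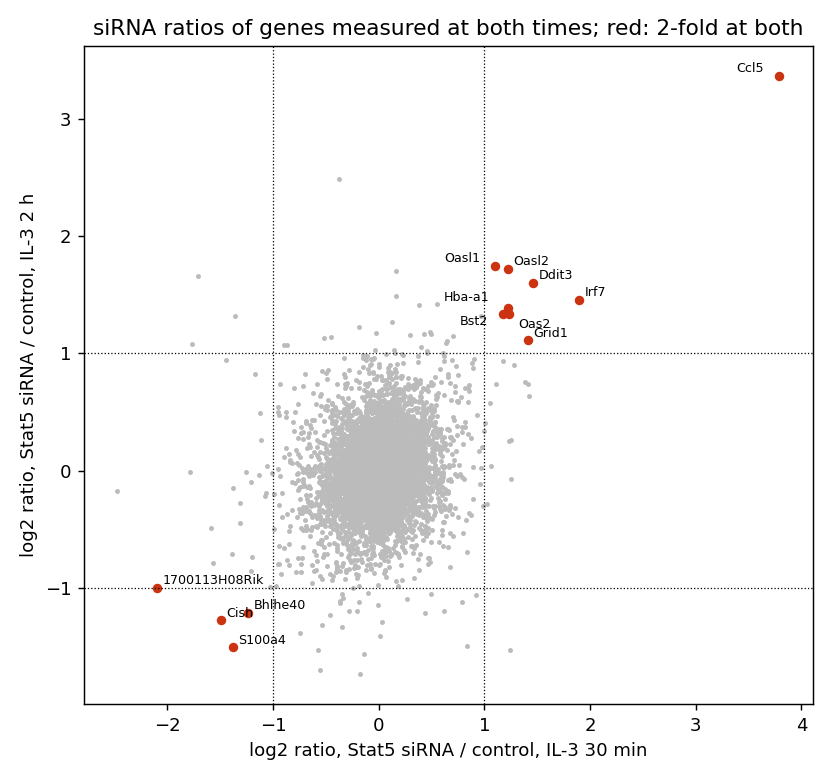
Log2 ratio of Stat5 siRNA to control siRNA at 30 min (x) and 2 h (y) for 7699 genes, 1 point each, with dotted lines at 2-fold. The 9 genes higher at both times include Ccl5 at 3.79 and 3.37, both lower bounds, and the 4 lower ones include Cish at -1.49 and -1.28.

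Genes induced by IL-3 and lower with Stat5 siRNA were the selection the study was designed for. At 30 min it held Cish, at 1097 with control siRNA and 389 with Stat5 siRNA, Bhlhe40 (1143 and 485) and Socs1, another feedback inhibitor of cytokine signalling (277 and 101). On U74C it held Gm128 (siRNA ratio -1.38), 1700113H08Rik (-2.09), Tox (-1.01), Ppil6 (-1.10) and 2700046A07Rik (at least 2.25-fold lower). Dnajc21, Chchd4 and Hmgb2 had 1 selected U74C probe set each, while their values as genes were -0.58 or lower, 0.18 and -0.78 or lower. At 2 h it held Cish (-1.28), Bhlhe40 (-1.21), Pim2 (-1.05), Lama5 (-1.01), Tnfrsf13b (-1.70), Kazn (-1.10) and Lgr4 (-1.20). C3ar1, the receptor for complement C3a, was at least 2.61-fold lower, Trio at least 2.19-fold and Fads6 at least 2.49-fold, and Slfn2 had a ratio of -1.24 or lower over its probe sets. From U74C came 6430571L13Rik (-1.33), 1700113H08Rik, Zfpm2, Sp9, Syt4, Exoc3l2 and Ces1d, of which the last 5 are lower bounds. For the other 8 of 26 genes at 2 h the value of the gene did not reach 2-fold in both comparisons. Enah was selected on U74B (-1.15) and U74C (-1.14), with a gene value just short of 2-fold. Hbegf was -0.89 or lower as a gene, Rrp36 -0.32 or lower, Tcn2 -0.13, Vps72 0.16, Itgb1bp1 0.16, Haus3 0.14 and Fundc1 0.28. The values of 1700113H08Rik, Ppil6, Slfn2, Fads6, Syt4, Exoc3l2 and Ces1d rest on probe sets that can cross-hybridise. Cish, Bhlhe40 and 1700113H08Rik were selected at both times.

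The selection held 17 probe sets at 30 min and 32 at 2 h, which stood for 11 and 26 named genes. The design text states 12 and 29, under filters that were not applied here. The probe set counts were no larger than those with the siRNA labels exchanged, 28 at 30 min and 35 at 2 h. Simulations without any siRNA effect gave 28.1 at 30 min and 29.4 at 2 h on average, and the mirror counts were 14 and 25. U74C held 13 of the 17 and 18 of the 32, with mirror counts of 13 and 18. The simulations gave 24.3 on U74C at each time, so their noise can be too wide on that design. On U74A and U74B alone the selection held 4 at 30 min and 14 at 2 h, the mirror counts were 1 and 7, and the simulations gave 3.78 and 5.09, with upper 2.5% limits of 9 and 9.03. The exchanged labels gave 15 and 15 there, but the exchanged counts of all designs include genes that Stat5 siRNA raised at both times, such as Ccl5, Ddit3 and Hba-a1, and Irf7 on U74C. In Stat5 siRNA cells with IL-3, 114 and 355 probe sets were 2-fold higher than in control siRNA cells without IL-3, next to 109 and 338 in control siRNA cells with IL-3, and the former mix effects of IL-3 and of the siRNA. Of the probe sets selected on U74A and U74B, 8 of 14 measured at the other time were at least 1.5-fold lower there too, against 2.29% of all measured ones and 8.90% of those induced but not selected. The 14 hold 12 distinct probe sets, 6 of them lower. On U74C 5 of 26 selected ones were lower at the other time, 19.2%, against 457 of 8159 measured ones and 17.5% of those induced but not selected.

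**Figure D4:**
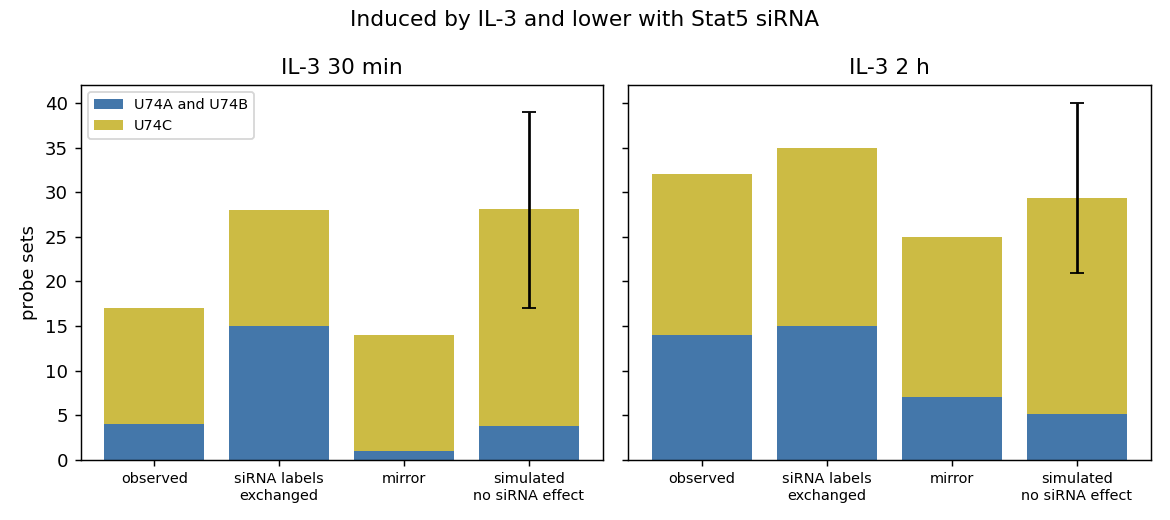
Probe sets induced by IL-3 and lower with Stat5 siRNA at 30 min (left) and 2 h (right), as observed, with siRNA labels exchanged, as the mirror selection, and as the mean of 200 simulations without siRNA effect, whose error bar leaves out 2.5% on either side; colours separate U74C from the other designs. The observed 17 and 32 lie under the exchanged 28 and 35.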

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

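The comparison of selected probe sets with their values at the other time and the erythroid check were chosen after their results had been seen, and so were the ratio of the interferon medians at the 2 times, these medians under quantile scaling, the comparison of interferon genes with unstimulated cells and the exchanged counts without repeated probe sets. The other tests here were written before the results they measure were seen.

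Several siRNA ratios pointed in opposite directions at 30 min and 2 h, and these differences were not tested. Psmc3 went from -1.71 to 1.66, a difference of 3.37, on 1 U74C probe set. Fbxo44 went from -1.77 or lower to 1.08 or higher, a difference of at least 2.85. Zfpm2 went from 1.24 or higher to -1.53 or lower, a difference of -2.77 or beyond. Both have a signal under the floor at each time. As lists, ribosomal proteins went from 0.12 to -0.15 with Stat5 siRNA, a difference of -0.27, and G2/M genes from 0.11 to -0.30 with IL-3, a difference of -0.40.

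Interferon response genes were higher with Stat5 siRNA at both times, and scaling of the arrays is argued against, since the list medians of 0.59 and 0.57 were 0.60 and 0.57 under quantile scaling, while its percentile, 100 throughout, can hardly respond to scaling. RNA of T, NK, myeloid, mast, fibroblast or epithelial cells is argued against, since of 97 marker probe sets under the floor in control siRNA cells with IL-3, erythroid ones included, 0 passed 2 times the floor with Stat5 siRNA, the highest being 111. Erythroid cells stay open, because Hba-a1 rose from 471 to 1103 at 30 min and the lower percentile of the erythroid list was 99.93, while most of its members did not reach 2-fold. A fall with IL-3 in control cells was not decided by the test written in advance. The interferon medians there were 0.07 at 30 min and -0.14 at 2 h, and percentile 13.52 at 2 h lay between its limits for and against. Against such a fall as the whole source stands that Stat5 siRNA cells with IL-3 lay 0.67 and 0.58 above unstimulated control cells. The median siRNA ratio at 30 min was 1.04 times that at 2 h, so the difference was already there early, and it may reflect the siRNA preparation itself or the loss of Stat5, which was not tested because no other Stat5 siRNA was analysed here.

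The probe sets induced by IL-3 and lower with Stat5 siRNA could come from noise of the control IL-3 array, which enters both ratios. On U74A and U74B the count with exchanged labels over both times was 30 against 18, which met what had been predicted in advance for noise, but most of the 30 were raised 2-fold by the siRNA at both times, such as Ccl5, Ddit3, Hba-a1 and Irf7, and without the probe sets that moved 2-fold the same way at the other time it was 12 against 14, so it decides nothing there. The simulation gave 24.3 on U74C at each time, above the 13 and 18 selected there, so its noise can be too wide. On U74A and U74B the selection held 4 at 30 min, near the 3.78 simulated from noise between probe sets, and 14 at 2 h, above the upper limit of 9.03 and the mirror count of 7, though the simulation leaves out variation between cell cultures. Against noise as the source of every member there stands that 57.1% of the selected probe sets were 1.5-fold lower at the other time, against 2.29% of all measured ones and 8.90% of those induced but not selected, and this rests on 12 distinct probe sets, 6 of them lower, so noise stays open for the others. On U74C the count was 33 against 31, as noise predicted, and 29 against 28 without such probe sets. At the other time 19.2% were lower, a larger share than the 457 of 8159 measured ones. It was close to the 17.5% of those induced but not selected, so noise stays open for that selection as a set. Single members did repeat on other arrays: 1700113H08Rik was selected at both times, and Enah at 2 h on U74B too. They do not settle the other members.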

How the results depend on the processing

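Results on U74A and U74B only, results without cross-hybridising probe sets and random lists matched on the IL-3 ratio were chosen after seeing the data. Of 1526 values under an alternative, 1383 kept their call, stayed within the spread between probe sets of 1 gene or, for counts, within 1.5 times, and 4 reversed. The 1526 leave out results that an alternative could not give, such as Stat5a without cross-hybridising probe sets. Genes read only on U74C are likewise not counted as lost on U74A and U74B only. No list median reversed its call (0 of 721). Median and quantile scaling, and a floor per design, left every count within 1.5 times. The counts depended on the floor, which by construction sets how many dim probe sets can reach 2-fold. Counts are given as higher and lower for IL-3 at 30 min, IL-3 at 2 h, siRNA at 30 min and siRNA at 2 h, then the induced and lower probe sets at 30 min and 2 h. With the floor halved they were 247 and 268, 614 and 614, 199 and 195, 272 and 256, then 58 and 85, and signals not raised to the floor give the same counts by construction. With the floor doubled they were 54 and 22, 183 and 113, 23 and 23, 27 and 25, then 8 and 11. On U74A and U74B only, with fewer probe sets, they were 44 and 12, 224 and 182, 18 and 15, 34 and 30, then 4 and 14. Without cross-hybridising probe sets the lower count for IL-3 at 30 min was 49, the siRNA counts at 30 min were 30 and 33, the lower siRNA count at 2 h was 43, and the induced and lower counts were 11 and 19. With a 1.5-fold siRNA threshold these were 40 and 75, against 41 and 69 with the siRNA labels exchanged. The STAT5 target list with siRNA at 30 min came to stand apart with the floor halved (-0.25), doubled (-0.19) or per design (-0.22), and with signals not raised to the floor (-0.27), and the cause was not tested. At 2 h its median of -0.24 no longer stood apart among lists matched on the IL-3 ratio (percentile 8.65). Those lists had lower siRNA ratios too (median -0.12), but they can hold other STAT5 targets, so the cause is not settled. Stat5a was -0.69 at 30 min and -0.49 at 2 h with the floor doubled, which then lies above the siRNA signal of 1 of its 2 probe sets. Fastk reversed to 0.23 with the floor halved and 0.22 with a floor per design, where its U74A probe set enters. Psmc3 reversed to 0.031 at 30 min and -0.082 at 2 h on U74A and U74B only, where its U74C probe set drops out. No paired analysis was possible because each condition has 1 array per design. Signal over background limits dim genes, for which only lower bounds are given.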

Other observations

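The probe sets and genes of the first paragraph were chosen after their values were seen, and no test was run on them. S100a4 was lower with Stat5 siRNA at both times without being induced by IL-3. Its signal was 1412 without IL-3, 1040 at 30 min and 1248 at 2 h with control siRNA, and 399 and 439 with Stat5 siRNA. Hba-a1 hardly moved with IL-3, at 467 without it and 471 and 447 with it, and was 1103 and 1172 with Stat5 siRNA. A U74A probe set that lists several genes went from 446 to 149 with Stat5 siRNA at 30 min and from 460 to 142 at 2 h, against 435 without IL-3. A U74C probe set without a gene in the annotation used here rose from 152 to 2200 with IL-3 at 30 min and was 926 with Stat5 siRNA. For Irf7 the value in the text came from a U74A probe set (41.4 and 447 at 30 min), while a U74C probe set that can cross-hybridise gave 1220 and 9276.

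The lists of apoptosis regulators, cholesterol and fatty acid synthesis, mitochondrial respiration and heat shock did not stand apart in any of the 4 comparisons with the settings of the report. Apoptosis regulators lay between percentile 4.88 and 95.9, cholesterol and fatty acid synthesis between 33.0 and 93.1, mitochondrial respiration between 15.4 and 55.9, and heat shock between 3.97 and 95.6. For IL-3 at 30 min, apoptosis regulators, cholesterol synthesis and heat shock genes came to stand apart upward on U74A and U74B only, and with Stat5 siRNA at 30 min cholesterol synthesis genes did so downward with the floor doubled. Few markers of other lineages were measured. With Stat5 siRNA at 30 min these were 2 genes of the pro-B and B lineage (median -0.25), 2 of the myeloid and mast (0.01), 1 of the T and NK (0.54) and 3 of the fibroblast and epithelial list (0.17), too few for a percentile. At 2 h they were 3 of the myeloid and mast (-0.21), 1 of the T and NK (-0.13), 2 of the fibroblast and epithelial (0.085) and 1 of the pro-B and B lineage list, Tcf3 (1.14). Tcf3 was read only from a U74C probe set that can cross-hybridise, and was -0.45 at 30 min.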
